A study of Rattus norvegicus with 15 samples.

How the data were processed

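RNA was measured in 15 sequencing libraries from primary rat oligodendrocytes, the cells that make myelin in the central nervous system. Per the labels' protocols, precursor cells from newborn rat forebrain cortex were matured in culture, and treated cultures received oligomeric amyloid-β. Libraries came from total cell RNA (input), from RNA immunoprecipitated with an antibody to the RNA-binding protein hnRNP A2, and from RNA recovered in a control immunoprecipitation with IgG. Per the labels' protocols, libraries were made with a stranded total RNA kit for very small inputs and read from both ends.

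The deposited files hold raw read counts, 1 value per gene identifier, as whole numbers that the authors had not normalized. Per the submitters' processing notes, STAR 2.7.1, HTSeq, R 4.2.2 and DESeq2 were used, and the notes give no role to any of them. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. Each deposited count table held 30560 rat Ensembl identifiers and 5 summary rows that name no gene. The summary rows held 76.0% to 85.5% of all records in the input libraries, 65.5% to 71.7% in the hnRNP A2 libraries and 68.2% to 91.4% in the IgG libraries. They were left out of library sizes and tests. The files do not pair identifiers with gene names. The RefSeq gene table for assembly GRCr8 used here gave no Ensembl identifier in any row, so 0 of the 30560 identifiers could be matched. The 21 gene lists fixed before the data were examined, and the genes of the myelin proteins and of hnRNP A2 itself, were therefore not analysed here.

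Samples were grouped by their titles and treatment labels into 5 groups of 3 libraries, with replicate numbers 2, 3 and 4 from the titles. The IgG libraries are a pool of both treatments per the labels, while their file names carry the mark of amyloid-β; the labels were followed. The series' design text calls the replicates biological. No 2 libraries of a group agreed within sampling noise in a chi-square comparison of their counts, so all 15 were kept as separate samples.

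All tests across genes used edgeR 4.0.16 in R 4.3.3, with TMM normalization, the package's default expression filter, quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05, without a replicate term. The hnRNP A2 and IgG libraries were fitted together, as were the hnRNP A2 and input libraries and the IgG and input libraries. The amyloid-β comparisons within input and within the hnRNP A2 immunoprecipitation used only their own 6 libraries. A standard error (SE) of a log2 fold change is its size divided by the square root of F. Values in CPM are counts scaled to a common library size with TMM factors. Measures of whole libraries were compared by 2-sided exact permutation tests, 20 in all, adjusted together. Paired exact tests by replicate number, of the treatment and of hnRNP A2 against input, were added after seeing the data, 12 in all, and the latter were adjusted over these 12. The number of genes at equal depth is the number expected in 80000 counts drawn from a library.

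The alternatives were DESeq2 1.42.0, limma 3.58.1 with voom and quality weights, DESeq2-type size factors, library sizes alone, no expression filter, a filter of at least 1 CPM in at least 3 libraries, a minimum log2 fold change of 1, all 15 libraries in 1 fit, the replicate number as a block, that block within each treatment where hnRNP A2 and input were fitted together, and each library left out. These choices and the rule for named genes were fixed before the data were examined. The rule takes the largest fold changes in each direction among genes past the threshold whose groups do not overlap and whose mean is at least 10 CPM in the higher group. Where none passes, it takes the smallest p-values. As fixed, the rule took more genes per direction, left out genes without a name and always named certain genes. Because no identifier has a name here, only its numeric part was used, with 2 genes per direction. Identifiers are printed for the comparison of hnRNP A2 with IgG alone, with 1 exception stated where it occurs.

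Whether replicate numbers pair the libraries was checked from the correlation of same-numbered libraries' deviations from their group means. It was 0.53 to 0.79 between the treatments in the hnRNP A2 immunoprecipitation and 0.34 to 0.58 in input. Between the hnRNP A2 immunoprecipitation and input, no same-numbered pair was under 0.15, and between hnRNP A2 and IgG the pairs lay from 0.12 to 0.25. Between IgG and input it fell to -0.06. Pairs of different numbers reached 0.26 between the treatments in the hnRNP A2 immunoprecipitation and 0.07 in input, below each same-numbered pair. They reached 0.28 between hnRNP A2 and input and 0.14 between hnRNP A2 and IgG, where they overlapped the same-numbered pairs. The numbers were read as pairing the libraries in every comparison but that of IgG with input. Only between the treatments do the correlations set same-numbered pairs fully apart. The pairing comes from the data and the titles, since no label states a shared culture. Counts of calls with the block had already been seen when this check was computed.

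Each fit was tested on simulated data with the real means and library sizes. Of 100 genes changed 4-fold, 70.0% were recovered for hnRNP A2 against IgG, 60.0% for the control immunoprecipitation against input, 54.0% for amyloid-β in input, 79.0% for amyloid-β in the hnRNP A2 immunoprecipitation and 28.0% for the interaction. Of 100 genes changed 2-fold, the respective shares were 22.0%, 12.0%, 3.0%, 20.0% and 1.0%. Genes left unchanged but called numbered 9, 4, 4, 2 and 3 in the same order, and 13 for hnRNP A2 against IgG with the replicate block. With the replicate block, 69.0% of 4-fold and 12.0% of 2-fold interactions were recovered.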

Results

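The series examined which RNAs are recovered with hnRNP A2 in oligodendrocytes, and whether oligomeric amyloid-β alters this. hnRNP A2 is an RNA-binding protein known for its part in transporting messenger RNA in these cells. There were 3 libraries each of control input, amyloid-β input, control hnRNP A2 immunoprecipitation, amyloid-β hnRNP A2 immunoprecipitation and IgG immunoprecipitation of both treatments pooled.

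Reads assigned to genes numbered 14773400 to 25751522 in the 6 input libraries and 28056346 to 33168494 in the 6 hnRNP A2 libraries. The IgG libraries were far shallower, with 81463 in replicate 2, 4096829 in replicate 3 and 1895870 in replicate 4. Between 16234 and 17593 genes had at least 1 count in an input library, 18033 to 19031 in a hnRNP A2 library and 8874 to 16005 in an IgG library. A count of 0 still allowed a level of up to 33.8 CPM in IgG replicate 2, against at most 0.107 CPM in the hnRNP A2 libraries. These limits cover counting error only.

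The makeup of the hnRNP A2 libraries lay apart from that of the input libraries without overlap, by 4 measures that pass as unpaired tests and not as paired ones. The 10 most abundant genes took 30.8% ± 8.16 (SD, n = 6) of gene counts in input and 7.54% ± 1.07 (SD, n = 6) in the hnRNP A2 libraries, with no overlap (exact permutation test, p = 0.00216, the smallest that 6 unpaired libraries against 6 allow; adjusted p = 0.0108). In the IgG libraries they took 11.2% ± 4.57 (SD, n = 3), lower than in each input library (exact permutation test, p = 0.0238, adjusted p = 0.0595, which does not pass). The pair of genes with the highest mean share in these input libraries was picked for that share. It made up 20.8% ± 7.60 (SD, n = 6) of input counts, 1.57% ± 0.196 (SD, n = 6) of hnRNP A2 counts and 1.61% ± 0.747 (SD, n = 3) of IgG counts. At an equal depth of 80000 counts, 9451 ± 123 genes (SD, n = 6) would be detected in the hnRNP A2 libraries and 8518 ± 301 (SD, n = 6) in input (exact permutation test, p = 0.00216, adjusted p = 0.0108). The IgG libraries had 9022 ± 183 (SD, n = 3), below each hnRNP A2 library and above each input library (exact permutation test, p = 0.0238 for both, adjusted p = 0.0595, which does not pass).

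Uniquely aligned reads outside annotated features were also a larger share in each immunoprecipitated library than in each input library. Their share was 22.6% ± 2.60 (SD, n = 6) in the hnRNP A2 libraries and 9.94% ± 1.13 (SD, n = 6) in input (exact permutation test, p = 0.00216, adjusted p = 0.0108). The IgG libraries had 20.2% ± 1.82 (SD, n = 3), and an unpaired test against the hnRNP A2 libraries did not pass (exact permutation test, p = 0.214, adjusted p = 0.390), although each IgG library lay below the mean of the hnRNP A2 libraries of its number. Alignments to several places made up 55.7% ± 7.04 (SD, n = 6) of aligned records in input and 18.9% ± 5.55 (SD, n = 6) in the hnRNP A2 libraries (exact permutation test, p = 0.00216, adjusted p = 0.0108). In the IgG libraries they ranged from 25.5% to 75.7%. Paired by treatment and replicate number, the 4 measures differed from input in 1 direction in 6 of 6 pairs, but each paired exact permutation test gave p = 0.0312, the smallest that 6 pairs allow, and an adjusted p of 0.0938, which does not pass. Averaged within the 3 replicate numbers, none can go below 0.25. None of these 4 measures passed a test between amyloid-β and control, where 3 libraries against 3 allow no p under 0.1 and 3 pairs none under 0.25. The number of genes at 80000 counts was higher with amyloid-β in each of the 3 same-numbered pairs, by 347 ± 302 (SD, n = 3) in input and 20.5 ± 19.3 (SD, n = 3) in the hnRNP A2 libraries (paired exact permutation test, p = 0.25 for both). The share of the top 10 genes was lower with amyloid-β in each input pair and higher in each hnRNP A2 pair.

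**Figure D1:**
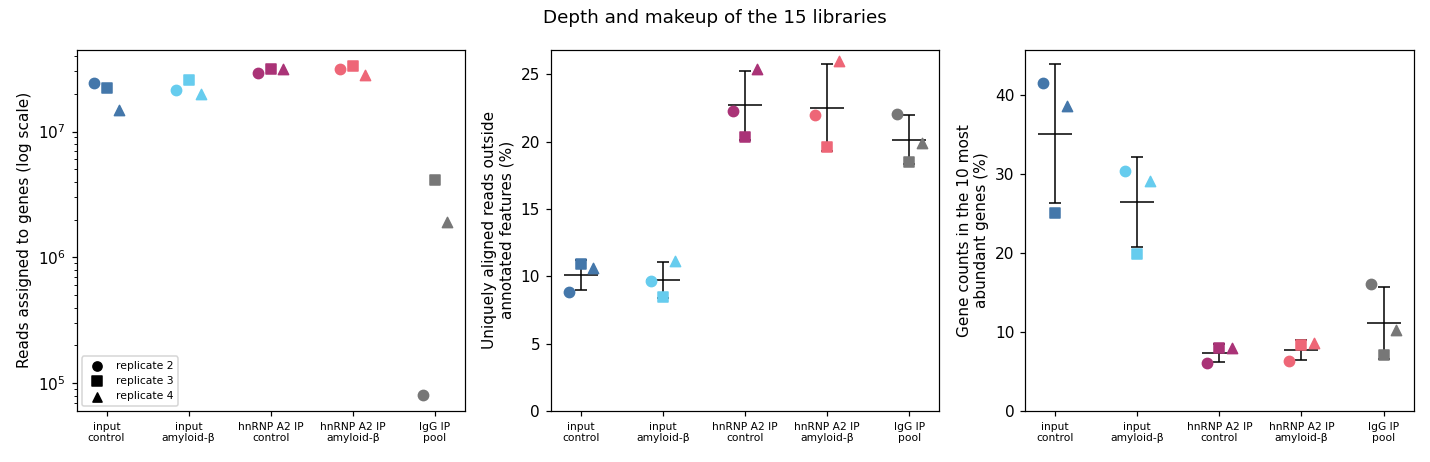
Each point is 1 library, with marker shape giving the replicate number; the panels show reads assigned to genes (log axis), uniquely aligned reads outside annotated features (%) and gene counts in the 10 most abundant genes (%), and bars in the latter 2 panels are the mean ± SD of 3 libraries. IgG replicate 2 lies lowest in depth at 81463 reads, and the hnRNP A2 libraries lie at 7.54% on average in the share of the top 10 genes against 30.8% in input.

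The comparison of hnRNP A2 with IgG asks which RNAs took a larger share with the antibody than in the background of the procedure. Scaling to a common library size removes differences in total yield, so a lower gene has a smaller share and not necessarily less RNA. Of 15304 genes tested with edgeR, 1192 were higher and 892 lower with hnRNP A2 than with IgG, 2084 in all. This fit takes the 6 hnRNP A2 libraries as independent, although same-numbered ones of the 2 treatments correlated at r = 0.990 to 0.993. It thus counts 3 replicate numbers as 6 samples. The higher genes had a median log2 fold change of 1.14 and the lower ones -1.04. ENSRNOG00000034234 was 13.9-fold higher, at 20124 ± 5719 CPM (SD, n = 6) with hnRNP A2 and 1438 ± 544 CPM (SD, n = 3) with IgG (log2 fold change 3.80, SE 0.42, edgeR adjusted p = 0.00240). ENSRNOG00000030700 was 11.7-fold higher, at 3016 ± 1137 CPM (SD, n = 6) against 246 ± 66.8 CPM (SD, n = 3), with an edgeR adjusted p of 0.00247. ENSRNOG00000058179 and ENSRNOG00000051703 were lower with hnRNP A2, with log2 fold changes of -4.54 (SE 0.75) and -4.53 (SE 0.88). They had 3 and 2 counts in the shallowest IgG library and kept the call without it. Both lost the call without IgG replicate 4, where their log2 fold changes were -3.37 and -2.28.

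The number of genes called against IgG rested on single libraries. Without IgG replicate 4 it fell to 21, and it was 1150 and 1063 without control hnRNP A2 replicates 3 and 4, and 1360 and 969 without amyloid-β hnRNP A2 replicates 3 and 4. With the replicate number as a block it was 5392, 2937 higher and 2455 lower, and 3731 with the block and without IgG replicate 4. Of the 2084 genes, 2083 were also called in the same direction with the block. They had been picked from the same libraries, and the blocked fit calls more genes, so this is no separate support. Without IgG replicate 4 all 2084 kept their sign, though they had been picked with that library included. With library sizes alone as the scaling, 1551 genes were higher and 648 lower, and with voom, a different model, 957 were higher and 1152 lower. DESeq2-type size factors gave 1215 higher and 940 lower.

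The IgG libraries are labelled as a pool of both treatments, but their file names carry the mark of amyloid-β, so a treatment difference may enter the control values against IgG. Set against IgG separately, the control immunoprecipitation had 650 genes higher and 379 lower, 1029 in all, and the amyloid-β immunoprecipitation had 690 higher and 463 lower, 1153 in all. By the rule for named genes, which leaves out low and overlapping ones, ENSRNOG00000034234 came first among the higher genes in both, with log2 fold changes of 3.73 (SE 0.44) in control and 3.86 (SE 0.44) in amyloid-β. With the replicate block the counts were 4854 in control and 4963 in amyloid-β. In control, edgeR called 0 genes without IgG replicate 4 and 0 without control hnRNP A2 replicate 3, with 2514 and 3211 genes at an unadjusted p under 0.05. The control count was 551 and 2 without control hnRNP A2 replicates 2 and 4, 517 and 232 without amyloid-β hnRNP A2 replicates 3 and 4, and 1943 without IgG replicate 3. In amyloid-β, edgeR called 0 genes without IgG replicate 4, with 2633 at an unadjusted p under 0.05. Without that library all 1029 control and all 1153 amyloid-β genes kept their sign, and 1014 and 1136 of them had an unadjusted p under 0.05. These genes had been picked with that library included, so this is no separate support for them. Their median absolute log2 fold change went from 1.26 to 1.10 in control and from 1.26 to 1.11 in amyloid-β. The amyloid-β count was 739, 179 and 3 without amyloid-β hnRNP A2 replicates 2, 3 and 4, 728 and 313 without control hnRNP A2 replicates 3 and 4, and 1944 without IgG replicate 3. No other tool was run on fits with a library left out. With library sizes alone the control split was 970 higher and 286 lower and the amyloid-β split 1064 and 362, and with voom they were 762 and 847, and 796 and 921. ENSRNOG00000034234 lost its call in control without control hnRNP A2 replicate 3 or 4 or IgG replicate 4 (edgeR adjusted p = 0.0585, 0.0510 and 0.1003), where its log2 fold change was 3.73, 3.54 and 3.58. In amyloid-β it lost the call without IgG replicate 4 (edgeR adjusted p = 0.0683), with a log2 fold change of 3.71.

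Against their own inputs, the immunoprecipitations differed at more genes. In control cells 2908 genes were higher and 2814 lower in the hnRNP A2 immunoprecipitation, 5722 of 15303 tested with edgeR. In amyloid-β-treated cells 2845 were higher and 3137 lower, 5982 in all. Of the genes higher in control, 2330 were also higher in amyloid-β, against 540.6 for independent lists, and 2390 lower genes were shared, against 576.9. These comparisons have no library in common, but they come from 1 fit and their libraries are paired by replicate number. Independent lists are therefore no firm baseline. Genes lower than input in control cells had a median input level of 45.8 CPM, against 16.9 CPM for the higher genes and 9.10 CPM for genes not called. This level is a mean over the inputs of both treatments. Control input is also 1 side of the comparison, so a high level there favours the lower class by construction. By the rule for named genes, the strongest gain in control was 18.1-fold, from 12.96 ± 2.93 CPM (SD, n = 3) in input to 236 ± 30.7 CPM (SD, n = 3), and the same gene rose 16.9-fold in amyloid-β. The strongest loss in control was a log2 fold change of -9.76 (SE 0.81), from 35.1 ± 22.9 CPM (SD, n = 3) in input, for a gene with 0 counts in at least 1 control hnRNP A2 library. With library sizes alone the control split was 5598 higher and 1042 lower and the amyloid-β split 4766 and 1591.

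Neither of the 2 genes named as higher than IgG passed as higher than input. ENSRNOG00000034234 had a log2 fold change of -0.09 (SE 0.37, edgeR adjusted p = 0.875) against input in control and 0.65 (SE 0.37, edgeR adjusted p = 0.189) in amyloid-β. ENSRNOG00000030700 was lower than input in control (log2 fold change -1.16, SE 0.40, edgeR adjusted p = 0.0344) and did not pass in amyloid-β (-0.43, SE 0.39, edgeR adjusted p = 0.417). In the IgG libraries both were below input, with log2 fold changes of -3.50 (SE 0.44) and -4.33 (SE 0.43).

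The IgG immunoprecipitation itself differed from input. Of 14205 genes tested with edgeR, 2025 were higher and 2316 lower, 4341 in all, and 2193 without IgG replicate 4. With library sizes alone the split was 3385 higher and 1213 lower, and with voom 2834 higher and 2445 lower. Fold changes of the control hnRNP A2 immunoprecipitation over control input followed those of IgG over amyloid-β input across 14181 genes (Pearson r = 0.67, Spearman rho = 0.69). These comparisons share no library, but their libraries share replicate numbers, and genes are not independent replicates. Of 2780 genes higher in the former and 1658 higher in the latter, 1066 were shared, against 325.0 for independent lists, and 3 genes higher in the former were lower in the latter.

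Genes higher in the hnRNP A2 immunoprecipitation than in both IgG and its own input numbered 284 in control cells and 242 in amyloid-β-treated cells. The control count also rests on IgG libraries whose file names carry the mark of amyloid-β. Independent lists would give 125.2 and 130.0. In 10 simulated sets of unchanged groups the count was 0, but at most 1 gene was called there between hnRNP A2 and IgG, so this is no baseline for long lists. Both comparisons use the same hnRNP A2 libraries, which are too few to split, so part of the excess over independent lists may come from sharing them. With the replicate block the counts were 1167 and 1040, with library sizes alone 652 and 537, with all 15 libraries in 1 fit 165 and 160, and with voom 468 in amyloid-β. Without IgG replicate 4 both fell to 0, and without IgG replicate 3 they were 530 and 517. The control count was 137, 0 and 0 without control hnRNP A2 replicates 2, 3 and 4, and 143 and 57 without amyloid-β hnRNP A2 replicates 3 and 4. The amyloid-β count was 138, 37 and 0 without amyloid-β hnRNP A2 replicates 2, 3 and 4, and 130 and 51 without control hnRNP A2 replicates 3 and 4.

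**Figure D2:**
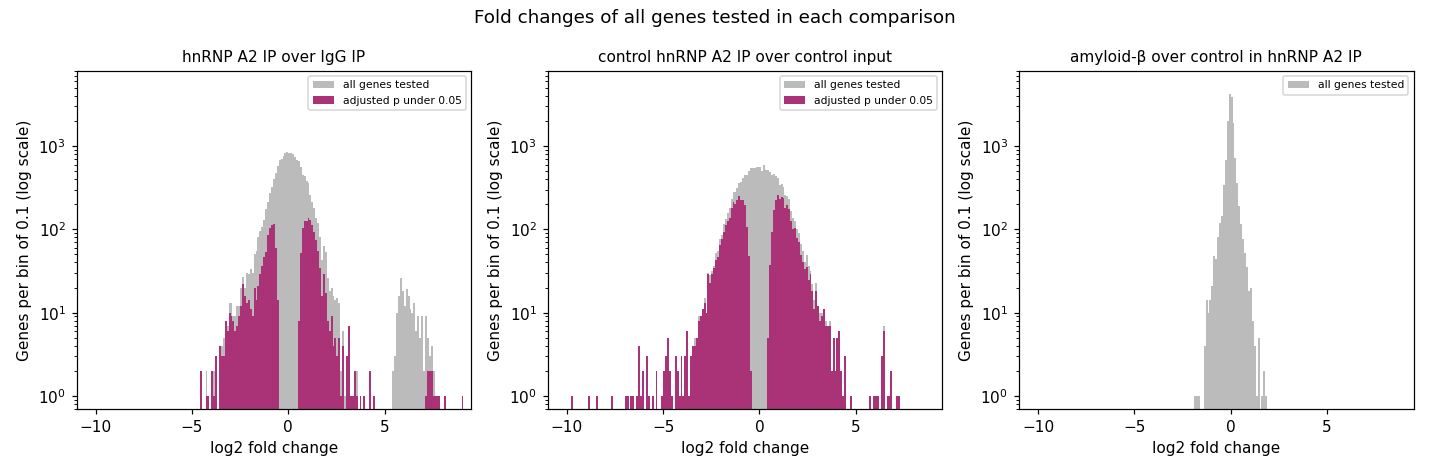
Histograms of log2 fold changes (bins of 0.1, gene counts on a log axis) for hnRNP A2 over IgG, control hnRNP A2 over control input, and amyloid-β over control in the hnRNP A2 immunoprecipitation, with all tested genes in grey and genes at an edgeR adjusted p under 0.05 in purple. The separate group at the right of the first panel is 215 genes with 0 counts in all IgG libraries, whose fitted values are not bounds and of which 13 were called; no gene is purple in the third panel.

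Amyloid-β changed no gene past the threshold in the input RNA. edgeR called 0 of 13793 genes, with 188 at an unadjusted p under 0.05, and DESeq2 and voom also called 0, with 335 and 210. With the replicate block edgeR called 0, with 1625 at an unadjusted p under 0.05 and a lowest adjusted p of 0.173. Without the block these counts were below the share of 0.05 that chance alone would give, and with it above. Genes are not independent, so that share is no test. The 95% confidence interval lay within a 2-fold change either way for 5653 genes, 41.0% of those tested, and for 9354 (67.8%) with the block.

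In the hnRNP A2 immunoprecipitation, amyloid-β again changed no gene past the threshold. edgeR called 0 of 15118 genes, with 42 at an unadjusted p under 0.05, and DESeq2 and voom called 0, with 35 and 133. The confidence interval lay within a 2-fold change for 10945 genes (72.4%), and for 13100 (86.7%) with the block. Those counts at an unadjusted p under 0.05 were below the share of 0.05 that chance alone would give. The block gave 888 such genes, slightly above that share. With the replicate block edgeR called 1 gene, ENSRNOG00000033299, which is named after its values were seen. It was 1.46-fold higher in amyloid-β (log2 fold change 0.55, SE 0.08, edgeR adjusted p = 0.00604), at 142, 260 and 201 CPM in amyloid-β replicates 2, 3 and 4 and 105, 154 and 146 CPM in the control replicates of those numbers. DESeq2 with the block, an alternative chosen after seeing the data, called 18 genes.

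The interaction asks whether amyloid-β changed the enrichment of a gene over its input. edgeR called 0 of 15303 genes, with 125 at an unadjusted p under 0.05, and DESeq2 and voom called 0, with 146 and 298. With the replicate block it called 0, with 279 at an unadjusted p under 0.05. All of these counts were below the share of 0.05 that chance alone would give. The confidence interval lay within a 2-fold change for 4476 genes (29.2%), and for 6758 (44.2%) with the block, so changes of that size were not excluded for most genes in either fit.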

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

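The tests of this result were chosen only after it was seen. The share of gene counts in the 10 most abundant genes was higher with amyloid-β than in control in each of the 3 same-numbered pairs of hnRNP A2 libraries, by 0.420 percentage points on average. In input it was lower in each of the 3 pairs, with a mean difference of -8.65 percentage points. The opposite directions drew attention to it, and the difference between them was not tested. Within each kind of library the treatment difference did not pass an exact permutation test (p = 0.5 in the hnRNP A2 libraries and 0.3 in input, with 0.1 the smallest possible). A paired exact permutation test gave p = 0.25 in both, the smallest that 3 pairs allow.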

How the results depend on the processing

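The replicate block with 1 IgG library left out and DESeq2 with the block were chosen after seeing the data; all other alternatives were planned. The planned gene list tests, and their alternatives, were not run because no identifier could be paired with a name. For hnRNP A2 against IgG the count of 2084 became 1262 with a log2 fold change of at least 1 and 5392 with the replicate block, and 5445, 5308 and 3731 with the block and without IgG replicate 2, 3 or 4. For control against IgG, 1029 became 1609 with voom, 583 with all 15 libraries in 1 fit, 4854 with the replicate block, and 4970, 5172 and 3331 with the block and without IgG replicate 2, 3 or 4. For amyloid-β against IgG, 1153 became 666 with all 15 libraries, 4963 with the replicate block, and 5058, 5155 and 3595 with the block and without those IgG replicates. Genes higher than both IgG and input, 284 in control and 242 in amyloid-β, became 159 and 140 with a log2 fold change of at least 1, 652 and 537 with library sizes alone, 165 and 160 with all 15 libraries, 1167 and 1040 with the replicate block, and 468 in amyloid-β with voom. Amyloid-β in the hnRNP A2 immunoprecipitation went from 0 to 1 gene with the replicate block and 18 with DESeq2 and the block. Apart from the settings with fewer libraries or a higher minimum, the cause was not tested.

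With each library left out in turn, hnRNP A2 against IgG ranged from 21 to 2428 genes, control against IgG from 0 to 1943, amyloid-β against IgG from 0 to 1944, control against input from 4234 to 6613, amyloid-β against input from 4243 to 6104, IgG against input from 2193 to 4806, and genes higher than both from 0 to 530 in control and 0 to 517 in amyloid-β. The lowest counts against IgG were without IgG replicate 4, and for control also without control hnRNP A2 replicate 3; the highest were without IgG replicate 3. Without IgG replicate 4, IgG against input gave 2193. The 2 amyloid-β comparisons and the interaction stayed at 0 in each such fit.

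The replicate block moved no other count by over 1.5 times. It gave 7465 and 7719 genes for control and amyloid-β against input, 0 for amyloid-β in input and 0 for the interaction. Within each treatment, the block gave 6697 and 6897 genes against input and 0 for the interaction. For IgG against input, where the numbers do not pair the libraries, it gave 5311. DESeq2 without the block, DESeq2-type size factors and both expression filters moved no total by over 1.5 times, though DESeq2 gave 647 in place of 379 lower genes for control against IgG. Library sizes alone moved the median log2 fold change of all genes by 0.63 and 0.49 for control and amyloid-β against input, 0.44 for IgG against input, 0.17 for amyloid-β in input, -0.13 for the interaction, and 0.11 for hnRNP A2 against IgG, and voom moved it by -0.17 for hnRNP A2 against IgG and 0.16 for IgG against input. For called genes named by the rule, 449 of 476 values under alternatives kept direction and call and 27 lost the call. All 27 losses were in comparisons of hnRNP A2 with IgG, where the same identifiers recur over overlapping comparisons. There ENSRNOG00000051703 in control kept the call in 14 of 20 settings. For uncalled genes named by the rule, 205 of 208 values were the same and 3 passed the threshold. Among called and uncalled genes, 0 values reversed. The depth of IgG replicate 2 limits what can be said of genes under 33.8 CPM in it.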

Other observations

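Leaving out single libraries and the replicate block were planned, and the thinning of the hnRNP A2 libraries and the comparison of different replicate numbers were set before their results were seen. The block with 1 IgG library left out and DESeq2 with the block were added after seeing the data, and the bounds applied to the counts without an IgG library, to the blocked counts and to the splits were chosen only after those counts were seen.

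The genes called between hnRNP A2 and IgG were weighed against 3 technical explanations. The shallowest IgG library is argued against as the source, since 2372 genes were called without IgG replicate 2. Greater hnRNP A2 depth as the whole cause is argued against by 1844 calls with the hnRNP A2 libraries thinned to the mean IgG depth. Of these calls, 1600 were among the 2084, with 11143 genes tested. The split became 915 higher and 929 lower, in place of 1192 and 892. That mean depth, 2024721 counts, still lies far above the 81463 of IgG replicate 2. A single IgG library as the source of the calls stays open in the unblocked test, where 21 were left without IgG replicate 4. With the replicate block the lowest count without 1 IgG library was 3731, but this does not decide the question. That fit draws its spread partly from same-numbered hnRNP A2 libraries of the 2 treatments, which correlated at r = 0.990 to 0.993. The IgG libraries correlated with each other at r = 0.753 to 0.930. Without IgG replicate 4, all 2084 genes kept their sign and 1907 had an unadjusted p under 0.05, while their median absolute log2 fold change went from 1.10 to 0.95 and their median SE from 0.25 to 0.29; these genes had been picked with that library included. Recovery through hnRNP A2 is the biological explanation the design names, and it stays open as a hypothesis.

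Differences from input that hnRNP A2 and IgG share were weighed next. Culture differences shared by libraries of one replicate number are argued against, since across 6 combinations of single libraries with different numbers on the 2 sides the median r was 0.470, from 0.191 to 0.557, with the 2 lowest values from IgG replicate 2. A common effect of the immunoprecipitation procedure, such as loss of the most abundant input RNAs, may contribute and was not tested, and neither was the part of hnRNP A2 binding.

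The lack of calls between amyloid-β and control was weighed against spread between replicate numbers hiding the treatment's effect. With the replicate number as a block, edgeR called 1 gene in the hnRNP A2 immunoprecipitation and 0 in input, in fits that recovered 99.0% and 93.0% of simulated 4-fold changes, which argues against many hidden changes of that size. Smaller changes hidden by this spread stay open. DESeq2 with the block called 18 genes in the hnRNP A2 immunoprecipitation, 17 higher and 1 lower, against 0 without it, and 0 in input. The blocked edgeR fits recovered 79.0% and 39.0% of simulated 2-fold changes.

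Other splits of the same libraries were counted. For hnRNP A2 against IgG, fitted here as 2 groups and therefore giving 2822 genes in place of 2084, 1 of 84 splits, the real one, gave as many, and the highest of the others gave 1573. Chance can be excluded only if the libraries are taken as freely exchangeable. Of the 27 splits that take 1 library from each replicate number, the real one gave the most and the highest other gave 0, but with the hnRNP A2 libraries of a number taken as 1 sample, 3 numbers are too few for a share under 0.05. The split with 1573 set the 3 immunoprecipitated libraries of replicate 2 apart, and those that set apart replicate 3 or replicate 4 gave 0. With IgG replicate 3 or 4 in place of IgG replicate 2 it gave 23 and 483. The count in these splits therefore depended on the IgG library as well as on the hnRNP A2 libraries of replicate 2. In the fit of 3 groups, which is not this one, the count is 2084 without the replicate block and 5392 with it. For IgG against input, again as 2 groups and giving 4496 genes in place of 4341, 1 of 84 splits reached the real count and the highest other, which set replicate 2 apart, gave 142, under the same limit. With 3 libraries against 3 the 10 splits are too few for a share under 0.05: the real counts were 1029 and 1153 for control and amyloid-β hnRNP A2 against IgG and 5722 and 5982 against input, each reached by 1 split and with a highest other of 0. For amyloid-β in input and in the hnRNP A2 immunoprecipitation, all 10 splits gave 0 genes, and for the interaction all 100 drawn splits gave 0. Every split reaches a real count of 0, so this says nothing about an effect.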
